A study of Mus musculus with 2 samples.

How the data were processed

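Nuclei of hippocampal tissue from mice whose Bcas2 gene is flanked by loxP sites were profiled in 2 libraries, 1 from mice injected with an adeno-associated virus carrying Cre under a synapsin promoter and 1 from mice injected with the vehicle virus. Per the labels' protocols, nuclei were released by douncing, stained with propidium iodide, sorted by flow cytometry to remove debris, and loaded on the 10x Genomics 3' V3 kit for an expected 8000 nuclei and at least 20000 reads per nucleus, with paired-end sequencing. The number of mice behind each library and the part of Bcas2 between the loxP sites are not given in the sources used here. The values the authors deposited are raw UMI counts per gene and barcode (UMI, unique molecular identifier), made with Cell Ranger 9.0.1 per the file headers, and not normalized. The submitters' processing notes also list bcl2fastq 5.0.1, Seurat 4.1.0 and the GRCm39 genome build. Whether intronic reads were counted and how barcodes were called is not given in the sources used here. The reference genome at hand is of another build, so no coordinates are printed, and gene symbols are those of the deposited tables (55357 genes in each).

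All steps from the counts on were run here with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9 and leidenalg 0.10.2, and with edgeR 4.0.16 in R 4.3.3 for scaling factors only. Nuclei were kept with at least 500 genes, at least 800 UMIs and under 5% mitochondrial UMIs. Doublets were marked with Scrublet in each library at an expected rate of 0.8% per 1000 barcodes. Its automatic threshold marked 1112 nuclei (8.28%) in the knockdown-labelled library and 0.016% in the control library. The rule for such a failure, fixed before the data were examined, was to mark the top scores at the expected rate, 10.1% for the control library. It marked 1366 nuclei (10.9%) there, because 128 nuclei tied at the threshold score were all marked. Counts were scaled to 10000 per nucleus and log-transformed. From 2000 variable genes, with Bcas2, mitochondrial and sex-linked genes left out, 30 principal components and 15 neighbours were taken, and Leiden clusters at resolution 1 were found on both libraries together without integration.

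Clusters were named from 226 markers of 23 classes fixed before the data were examined. A cluster took the class whose markers had the highest mean log2 fold over the median of the other clusters, with 5 added to each CPM value. It stayed unnamed with under 3 markers detected in 5% of its nuclei, with under 3 markers among its leading 100 genes, or where its top 10 genes held more markers of another class. It also stayed unnamed with a median depth under 1/3 of that of its own library and no marker in its top 10 genes. This scoring was set after a first clustering had been seen, in which a fold over all other nuclei left an oligodendrocyte cluster of 2064 nuclei without a name. Of 37 clusters, 8 stayed unnamed. They held 14.9% of the nuclei of the knockdown-labelled library and 1.37% of the control. A class was compared between the libraries with at least 100 nuclei in each, which 6 classes had.

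With 1 library per group there is no spread between animals, so no test was made and no p-value is given. UMIs were summed per library and class and scaled to the total of the class (CPM) with exact Poisson intervals, shares of nuclei with exact Clopper-Pearson intervals, and ratios with exact conditional binomial intervals, all at 95%. These intervals cover counting error only. Log2 ratios are of the knockdown-labelled library over the control, with 0.5 UMI added for single genes outside the 3 key genes. For each of 25 gene lists and 6 classes, the median log2 ratio over genes with at least 50 UMIs was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. The lists were BDNF-TrkB signalling, adult neurogenesis, excitatory postsynapse, presynaptic release, GABA receptors and synapse, voltage-gated channels, immediate early genes, Prp19 complex and spliceosome, splicing regulators, p53 and apoptosis, integrated stress and unfolded protein response, heat shock and chaperones, axon injury and regeneration, interferon response, disease-associated microglia, homeostatic microglia, reactive astrocyte, astrocyte homeostasis, myelin, oxidative phosphorylation, cytosolic ribosome, amyloid and Alzheimer genes, Wnt and beta-catenin, autophagy and lysosome, and sex-linked genes. Of their symbols, 6 were not found among the gene names and were left out.

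Genes named in the text followed a rule fixed before the data were examined. In each compared class, genes were ranked by log2 ratio among those with 100 UMIs and detection in 5% of nuclei in the library where they were higher. Their level there had to reach 0.25 of that in every other compared class of the same library. The 10 highest and 10 lowest were named in dentate gyrus (DG) granule-like nuclei and the 5 highest and 5 lowest in the other classes, leaving out mitochondrial, sex-linked and unnamed gene models. Up to 10 genes per direction at least 1.5-fold apart in the same direction in every compared neuronal class were named, as were up to 4 members of each described list and always Bcas2, Bdnf and Ntrk2. Of the genes that this rule named, 1 is not reported here. Syt1, Mobp and Mbp, given for RNA of other classes, were chosen after their values were seen, as were Gadd45b and Bcl2l11 among p53 and apoptosis genes. For the genes shared by the neuronal classes, the level and detection criteria were added after a first list without them had been seen.

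The steps were tested on simulated data, with Poisson counts drawn from the DG granule-like sums and 200 genes changed by known folds. Of the changed genes with enough UMIs, the interval held the true fold in 96.9% of 64 genes at 1.5-fold, 93.8% of 64 at 2-fold and 94.8% of 58 at 4-fold, and in 95.8% of 13248 unchanged genes. Over 20 simulations without any change, 6.8% of 500 list medians lay outside the central 95% of the random lists, and a list shifted by 0.58 on the log2 scale was found at 0.59. Each gene was drawn independently from 1 pooled profile, without free RNA that differs between the libraries. The simulation therefore checks the computation only. It does not calibrate the percentiles given below for lists whose members vary together.

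Alternatives fixed before the data were examined were a looser nuclei filter (200 genes, under 20% mitochondrial UMIs, no UMI minimum), a stricter one (1000 genes and 2000 UMIs), doublets kept, Leiden resolutions of 0.5 and 2, log values centred per library before clustering, edgeR's TMM scaling, nuclei thinned to 1000 UMIs, the mean CPM over nuclei, and gene minimums of 200 UMIs or of 1 UMI in each library. Alternatives chosen after seeing the data were a subtraction of free RNA in DG granule-like and GABAergic-like nuclei at 2 estimates of its share, nuclei split by sex (at least 2 Xist UMIs, or 1 Y-linked UMI), thinned nuclei with the genes of the unthinned sums, shorter lists of granule-lineage genes for neuroblast-like nuclei, and a level of 0.25 of that in every cluster of 50 or more nuclei for named genes. The subtraction took the share of free RNA in a class from markers of other classes relative to the whole library, as their median or, for a lower estimate, their lower quartile. It was first run in all 6 classes and then kept to the neuronal ones, because in glia many such markers are expressed by the cells themselves. Neurons are not free of this. Adarb2, a GABAergic-like marker, was among the leading genes of the DG granule-like cluster, so the share of free RNA there may be set too high. The lower estimate, and the limit of list medians by sex to DG granule-like nuclei, were also set after first results, and immediate early genes were counted among the main results only after they had been seen high. TMM scaling moved all log2 ratios by -0.25 in oligodendrocyte-like, -0.17 in microglia-like and -0.11 in astrocyte-like nuclei, and by -0.00014 in DG granule-like nuclei. Thinning left out 0 to 24 nuclei of a class, those under 1000 UMIs. A list median that turned sign without leaving the random range was counted as kept, and one that left it on the other side of 0 as moved.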

Results

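The study asked what loss of Bcas2, a component of the Prp19 splicing complex, does to cells of the mouse hippocampus, and its title names BDNF and its receptor TrkB, adult neurogenesis and Alzheimer's disease. The series used here holds 2 single-nucleus RNA libraries of hippocampus from mice with a floxed Bcas2 gene. In 1 of them the mice had received AAV2/9 with Cre under the synapsin promoter, which is active in neurons, and it carries the label Bcas2 knockdown. The other, from mice given the vehicle virus, is the control. Its genotype label reads WT, while its title and the design text name floxed mice for both libraries, and the labels do not settle this. The knockdown-labelled library held 16693 barcodes and 90594923 UMIs (median 4399 per barcode), and the control 12621 barcodes and 41781481 UMIs (median 2567). After filters and doublet removal, 12317 nuclei (median 5792 UMIs) and 11162 nuclei (median 2482 UMIs) remained. All values below describe these 2 libraries. With 1 library per group, differences have no replicate check, and the intervals cover counting error only.

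In DG granule-like nuclei, the principal neurons of the dentate gyrus, the level of Bcas2 (ENSMUSG00000005687) was 33.5 CPM (95% interval 30.5 to 36.8, 439 UMIs) in the knockdown-labelled library and 34.5 CPM (29.1 to 40.6, 143 UMIs) in the control, a log2 ratio of -0.041 (-0.32 to 0.24). In GABAergic-like nuclei it was 46.2 against 44.5 CPM (log2 ratio 0.054, -0.37 to 0.51). Over all neurons, meaning the named neuronal classes pooled, it was 39.9 against 35.3 CPM (0.18, -0.012 to 0.37). The interval lay above 0 under several alternatives, such as TMM scaling (0.23, 0.036 to 0.42) and libraries centred before clustering (0.28, 0.083 to 0.47). The pooled value also depends on the mix of classes, which differed. DG granule-like nuclei were 538 of the 920 neurons in the control and 1988 of 6955 in the other library. Within DG granule-like and GABAergic-like nuclei the main ratios lay within counting error, so the pooled value is not read as a rise within neurons. With nuclei thinned to 1000 UMIs the log2 ratio was -0.56 (-1.30 to 0.22, 55 and 22 UMIs) in DG granule-like nuclei, -1.13 (-2.04 to -0.082, 95 and 11 UMIs) in GABAergic-like nuclei and -0.23 (-0.70 to 0.26) over all neurons. In non-neuronal nuclei, outside the neurons the promoter targets, Bcas2 was higher in the knockdown-labelled library, with 46.1 against 29.5 CPM (0.65, 0.47 to 0.82). By class the log2 ratio was 0.66 (0.43 to 0.89) in oligodendrocyte-like, 1.30 (0.66 to 1.95) in astrocyte-like and 1.22 (0.58 to 1.85) in microglia-like nuclei, and 0.31 (-0.28 to 0.88), within counting error, in OPC-like nuclei (oligodendrocyte precursors). The microglia-like value was 0.57 (-0.68 to 1.67) with the stricter nuclei filter and 0.62 (-0.39 to 1.54) with nuclei thinned, the oligodendrocyte-like one 0.31 (-0.051 to 0.66) in male nuclei, the OPC-like one 0.47 (0.025 to 0.91) with doublets kept, and the pooled one 0.43 with TMM scaling and in male nuclei. These 3' tags do not show whether the floxed part of the gene was removed, since that part is not given in the sources used here and a tag outside it checks nothing. The library is therefore called knockdown-labelled throughout, and each direction below rests on that label.

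The 2 libraries differed in which cells they held. Neurons of the named classes made up 56.5% (55.6 to 57.3) of the nuclei in the knockdown-labelled library and 8.24% (7.74 to 8.77) in the control. Oligodendrocyte-like nuclei, the myelinating glia, made up 16.9% (16.3 to 17.6) and 62.9% (62.0 to 63.8). DG granule-like nuclei made up 16.1% against 4.82%, GABAergic-like nuclei 15.8% against 0.923%, and subiculum or cortex excitatory-like nuclei 14.7% against 0.851%. CA1-like pyramidal nuclei numbered 843 against 15 and CA3-like nuclei 297 against 5, too few in the control to compare. Microglia-like nuclei made up 2.22% against 9.84%, astrocyte-like nuclei 4.45% against 5.94%, and OPC-like nuclei 2.69% against 6.003%. Cajal-Retzius-like neurons went the other way from the remaining neurons, with 0.552% against 1.47%. Neuroblast-like nuclei numbered 3 (0.0244%, 0.00502 to 0.0712) in the knockdown-labelled library and 89 (0.797%, 0.641 to 0.980) in the control, or 0.151 and 16.5 per 100 DG granule-like nuclei. The counts were 8 and 90 with the looser filter, 11 and 70 with the stricter one, 16 and 88 with doublets kept, and 0 (which allows up to 3) and 122 with libraries centred, so that the rate per DG granule-like nucleus in the knockdown-labelled library was at most 0.0524 of that in the control. Fibroblast-like (0.714% against 1.79%), endothelial-like (0.503% against 1.06%) and perivascular macrophage-like nuclei (0.106% against 0.439%) were also less frequent in the knockdown-labelled library.

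**Figure D1:**
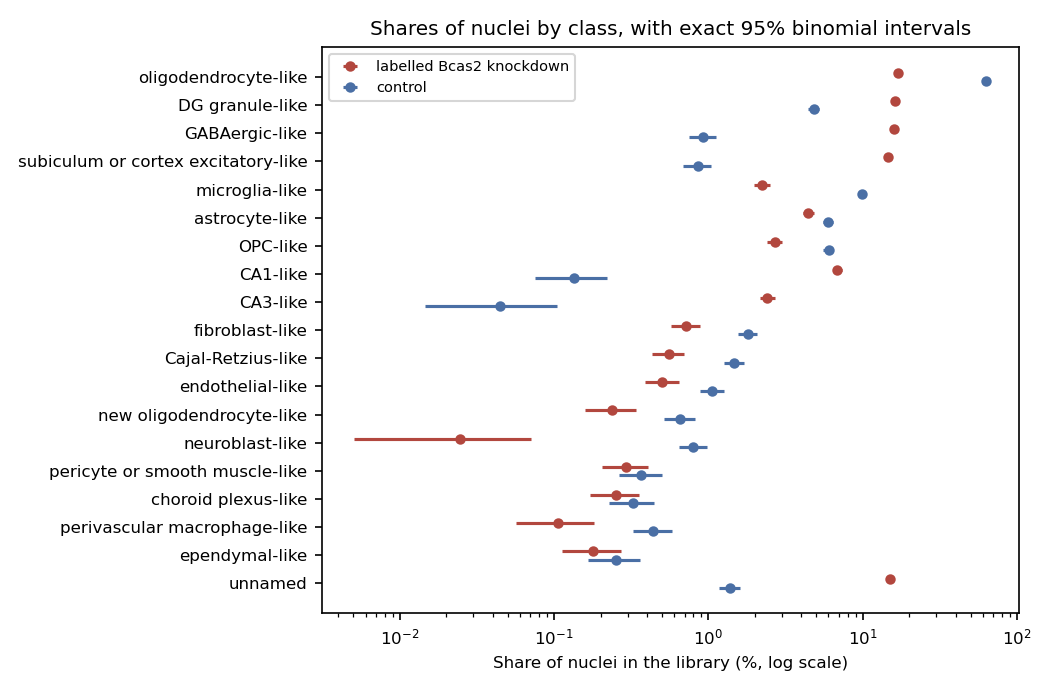
Share of nuclei in each library (percent, log axis) by class, with exact 95% binomial intervals, for the knockdown-labelled library (red) and the control (blue). Oligodendrocyte-like nuclei stand at 16.9% and 62.9%, DG granule-like nuclei at 16.1% and 4.82%, and neuroblast-like nuclei at 0.0244% and 0.797%.

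Dissection and the sort of propidium iodide-stained nuclei can each set such shares. No marker class was set for striatum, septum or pineal gland, so nuclei from such tissue could take another name or none. In the knockdown-labelled library and the control, unnamed cluster 20 (227 and 17 nuclei) had Rarb, Rgs9 and Gnal among its leading genes. Unnamed cluster 27 (65 and 53) had Drd3 and Isl1, and unnamed cluster 35 (8 and 20) Sag and Tph1. The compared GABAergic-like class was mixed too. Its cluster 11 (608 and 19) had Prdm16 and Zic1 among its leading genes, and its cluster 13 (521 and 49) Zfhx3. Their GABAergic-like markers had mean log2 folds of 1.67 and 2.10, against 3.14 and 3.87 in clusters 16 and 17 of that class. Whether any of these clusters came from beside the hippocampus was not tested. With the looser filter, which has no UMI minimum, the gap in neurons was 37.5 points in place of 48.2 and that in oligodendrocyte-like nuclei -49.5 in place of -46.0. The main filter removed 3264 barcodes (19.6%, median 629 UMIs) of the knockdown-labelled library and 93 (0.737%) of the control. Unnamed clusters held a further 14.9% and 1.37% of the nuclei. By markers, the nearest class of every unnamed cluster but cluster 35 was neuronal. The shares of neurons given here, and the gap between them, leave such nuclei out. Within every compared class, the control's nuclei were deeper. Median UMIs were 6275 and 7241 in DG granule-like, 1968.5 and 2314 in oligodendrocyte-like, and 3026 and 3957.5 in OPC-like nuclei. The same classes could be held by different clusters. Cluster 4 held 83.7% of the oligodendrocyte-like nuclei of the knockdown-labelled library and 0.712% of those of the control, and cluster 12 held 86.5% and 33.5% of the microglia-like nuclei.

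RNA of the cells that dominated each library was also found in its other classes. Syt1, a synaptic vesicle protein of neurons, stood at 461 to 686 CPM in the glial classes of the knockdown-labelled library and at 53.9 to 97.0 CPM in those of the control. Of 2 myelin genes of oligodendrocytes, Mobp stood at 12.4 CPM in DG granule-like nuclei of the knockdown-labelled library and at 98.1 CPM in those of the control, and Mbp at 115 and 301 CPM. In DG granule-like nuclei, markers of other classes stood at a median of 26.6% of their level in the whole library in the knockdown-labelled library and at 14.7% in the control. These values are the background against which the differences below stand.

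**Figure D2:**
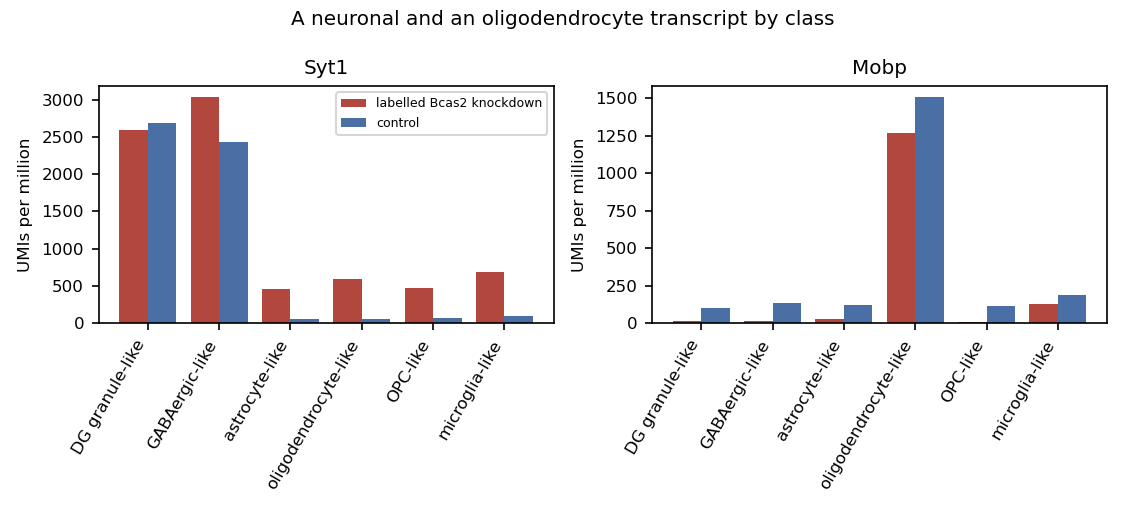
CPM of Syt1 (left) and Mobp (right) by class in the knockdown-labelled library (red) and the control (blue). Syt1 in glial classes reaches 461 to 686 in the knockdown-labelled library and 53.9 to 97.0 in the control, while Mobp in DG granule-like nuclei is 12.4 and 98.1.

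Bdnf (ENSMUSG00000048482), the neurotrophin named in the title, stood at the same level in DG granule-like nuclei of both libraries within counting error, with 66.3 CPM (62.0 to 70.9, 869 UMIs) against 67.3 CPM (59.6 to 75.6, 279 UMIs) and a log2 ratio of -0.020 (-0.22 to 0.18). In GABAergic-like nuclei its level was 9.74 against 12.98 CPM (-0.41, -1.20 to 0.49), and the log2 ratio went from -2.18 with the lower free RNA subtraction, -0.94 in male nuclei and -0.90 as mean CPM over nuclei to 0.33 with libraries centred before clustering and 2.34 in female nuclei, the last from 1 control UMI. The lower GABAergic-like level of the knockdown-labelled library lay within counting error and moved with the setting, so it is not read as a difference in expression. In oligodendrocyte-like nuclei, which should lack it, Bdnf was 17.3 against 2.99 CPM. Such RNA in GABAergic-like nuclei would raise, not lower, the level in the knockdown-labelled library. The source of the Bdnf RNA in glia is open. Over all neurons pooled it was 34.2 against 46.4 CPM (-0.44, -0.61 to -0.27), with DG granule-like nuclei being 538 of the 920 neurons in the control and 1988 of 6955 in the other library.

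Ntrk2 (ENSMUSG00000055254), which encodes TrkB, was higher in DG granule-like nuclei of the knockdown-labelled library, with 276 CPM (267 to 285) against 213 CPM (199 to 227), a log2 ratio of 0.38 (0.27 to 0.48). In oligodendrocyte-like nuclei it was 108 against 30.6 CPM, a difference of similar size in CPM. Subtraction of free RNA, chosen after seeing the data, turned the DG granule-like log2 ratio to -0.16, or to 0.13 with the lower estimate. In GABAergic-like nuclei Ntrk2 was 755 against 664 CPM (0.19, 0.078 to 0.30) and in astrocyte-like nuclei 1310 against 1219 CPM (0.10, 0.021 to 0.19). The first turned to -0.11 at a higher clustering resolution and to -0.12 with libraries centred, and the second to -0.0070 under TMM scaling and -0.027 in male nuclei.

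**Figure D3:**
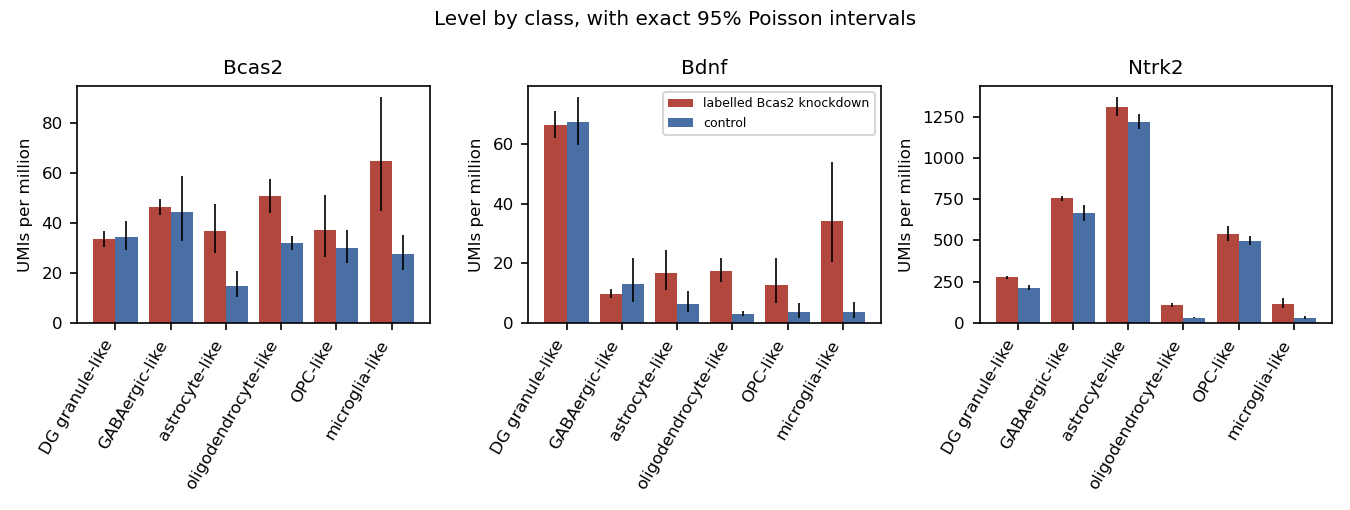
CPM of Bcas2, Bdnf and Ntrk2 in the 6 compared classes, with exact 95% Poisson intervals, for the knockdown-labelled library (red) and the control (blue). In DG granule-like nuclei Bcas2 is 33.5 and 34.5, Bdnf 66.3 and 67.3, and Ntrk2 276 and 213.

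In DG granule-like nuclei the BDNF-TrkB signalling list had a median log2 ratio of -0.075, at percentile 2.95 of matched random lists. Of its 30 measured members 2 were at least 1.5-fold higher and 3 lower in the knockdown-labelled library. Gab1, an adaptor of receptor tyrosine kinases (-2.81), and Pik3r1, a regulatory subunit of PI3 kinase (-0.79), were lower, and Hras (0.91) and Shc3 (0.67) higher. In the control, Gab1 and Pik3r1 reached only 0.05 and 0.09 of their level in the cluster where they were highest. Free RNA subtraction at its median estimate put Pik3r1 at 0.017 and Shc3 at -0.15. The median fell outside the random range in 6 of 16 alternatives, and was -0.20 with nuclei thinned to 1000 UMIs. The adult neurogenesis list lay inside the random range (median -0.032, percentile 13.3), with 3 of 18 members higher, among them Stmn2 (1.94) and Tubb3 (1.24), and 2 lower. Its median was 0.23 (percentile 89.2) with nuclei thinned to 1000 UMIs. The list of the Prp19 complex and spliceosome, to which Bcas2 belongs by function, had a median of 0.13 (percentile 95.6) with 1 of 32 members past 1.5-fold, the core spliceosomal protein gene Snrpd3 (1.09). It lay above the random range with doublets kept (0.15, percentile 97.7) and with both free RNA subtractions (0.18 and 0.17, percentiles 98.3 and 98.5). Splicing regulators had a median of 0.012 (percentile 68.5), and none of 33 reached 1.5-fold in either direction. In glia this list lay above the random range, at 0.091 in astrocyte-like, 0.15 in oligodendrocyte-like, 0.15 in OPC-like and 0.19 in microglia-like nuclei. Most members there were within 1.5-fold. TMM scaling turned the astrocyte-like median to -0.020 and the oligodendrocyte-like one to -0.10.

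Immediate early genes, which neurons induce on activity, had a median log2 ratio of 0.67 (percentile 99.99) in DG granule-like nuclei, and were high in other classes too. Medians were 0.55 (percentile 99.2) in astrocyte-like, 0.49 (percentile 97.6) in OPC-like and 0.56 (percentile 93.4, inside the range) in microglia-like nuclei. The astrocyte-like call ended with nuclei thinned (0.38) and the OPC-like one as mean CPM over nuclei (0.41) and with the looser filter (0.49, percentile 97.4). In DG granule-like nuclei 10 of 17 measured members were at least 1.5-fold higher and none lower. Fos was 8.78 against 0.723 CPM (3.39, 2.02 to 5.90, from 115 and 3 UMIs), Egr4 10.2 against 1.69 CPM (2.49), Arc 12.1 against 2.65 CPM (2.13) and Nr4a1 14.96 against 4.58 CPM (1.67). The same list had medians of 0.35 (percentile 99.2) in GABAergic-like nuclei, inside the random range with free RNA subtracted (0.14, or 0.22 with the lower estimate), nuclei thinned (0.11) or as mean CPM over nuclei (0.29), and of 2.07 in oligodendrocyte-like nuclei, against the background of neuronal RNA given above. A cluster of 21 nuclei of the knockdown-labelled library and 1 of the control, with Npas4, Fosb, Egr3 and Egr4 among its leading genes, stayed unnamed and was not part of the class. With a clustering resolution of 0.5 the DG granule-like median was 1.22, and with doublets kept 1.30. Subtraction of free RNA turned the DG granule-like median to -0.19, and to 0.32 (percentile 96.6) with the lower estimate. It was -0.054 in thinned nuclei, where 5 members were left, and 0.65 there with the genes of the unthinned sums.

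Oxidative phosphorylation genes had a median of 0.33 (percentile 100) in DG granule-like nuclei, 6 of 25 at least 1.5-fold higher and none lower. Ndufa4 (1.09), Uqcrb (0.93) and Cox5a (0.69), subunits of the respiratory chain, were among them. Cytosolic ribosome genes had a median of 0.25 (percentile 99.98), with 5 of 39 higher, among them Rpl13a (1.27) and Rplp1 (0.82), and in female nuclei the median was 0.16, inside the random range (percentile 96.8). In GABAergic-like nuclei both lists lay inside the range (percentiles 96.9 and 81.1), with 5 ribosome genes at least 1.5-fold lower and 1 higher, though oxidative phosphorylation left it with the looser (0.22) and stricter (0.25) filters and as mean CPM over nuclei (0.39). Neither list was high in DG granule-like nuclei alone. Oxidative phosphorylation genes lay above the range in all 4 glial classes, with medians of 0.76 in oligodendrocyte-like, 0.53 in OPC-like, 0.48 in microglia-like and 0.39 in astrocyte-like nuclei, and 8 to 17 members per class at least 1.5-fold higher and none lower. Ribosome genes did so in astrocyte-like (0.58), OPC-like (0.56) and oligodendrocyte-like nuclei (0.40), with 10 to 18 higher and at most 1 lower, and in microglia-like nuclei lay inside it (0.19, percentile 95.1), but above it with the looser filter (0.22) or nuclei thinned (0.28). The OPC-like calls ended with nuclei thinned (0.075 and 0.33) and over genes with 200 UMIs (0.17 and 0.25), and that of oxidative phosphorylation in microglia-like nuclei with the stricter filter (0.28) and doublets kept (0.30). Over all nuclei, mitochondrial UMIs made up 0.087% in the knockdown-labelled library and 0.059% in the control, and Malat1 7.67% and 10.98%. The class mix differed too. Whether the 2 lists follow how the nuclei were prepared was not tested. The p53 and apoptosis list had a median of 0.26 (percentile 97.8), with 4 of 20 members at least 1.5-fold higher, the proapoptotic genes Bax (0.70) and Bbc3 (0.66), the kinase gene Plk2 (0.65) and Gadd45b (1.89), 1 lower, Bcl2l11 (-0.61, -1.36 to 0.21), and 15 within 1.5-fold. It fell inside the random range in most alternatives, at percentile 77.7 when doublets were kept.

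Both stress lists had medians below the random range in DG granule-like nuclei, though most members were within 1.5-fold. The integrated stress and unfolded protein response list had a median of -0.27 (percentile 0.05), with 4 of 16 members at least 1.5-fold lower, among them the disulfide isomerase gene Pdia4 (-0.84). Within 1.5-fold, Ddit4 stood at -0.47, Hyou1 at -0.40 and Asns at 0.41 (-0.072 to 0.95). Heat shock and chaperone genes had a median of -0.22 (percentile 0.25), with 2 of 12 at least 1.5-fold lower, Cryab (-3.09) and Hsph1 (-0.66), and Hsp90ab1 at 0.52. Cryab is abundant in oligodendrocytes and reached 0.06 of its highest cluster level here. With nuclei thinned to 1000 UMIs and the same genes, both medians lay inside the random range, at -0.13 (percentile 19.2) and -0.058 (percentile 30.2). Free RNA subtraction gave -0.078 for the stress list (percentile 11.7), but -0.20, still below the range (percentile 0.53), with the lower estimate, and in male nuclei the heat shock median was -0.052 (percentile 21.4). Neither list was low in DG granule-like nuclei alone. Heat shock genes lay below the range in every compared class but OPC-like (-0.048), such as microglia-like (-0.41) and astrocyte-like nuclei (-0.21). The stress list did so in OPC-like nuclei (-0.30). These microglia-like, astrocyte-like and OPC-like calls ended with nuclei thinned (-0.13, -0.17 and -0.50).

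Synaptic lists lay inside the random range in DG granule-like nuclei, though not under every alternative. Excitatory postsynapse genes had a median of 0.031 (percentile 78.6), all 29 within 1.5-fold, with Camk2b (0.54) and Grik2 (-0.34) among the farthest. Presynaptic release genes stood at 0.10 (percentile 97.2), GABA receptor and synapse genes at 0.098 (percentile 95.3) and voltage-gated channels at -0.017 (percentile 41.2). The first 2 lay above the range with doublets kept (0.12 and 0.14), presynaptic release also with the looser filter (0.10, percentile 97.6), and channels below it with free RNA subtracted (-0.18), though not with the lower estimate (-0.094). Amyloid and Alzheimer genes stood at -0.058 (percentile 10.8), with 1 of 26 measured members at least 1.5-fold higher, Itm2c (0.91), and none lower. Picalm was at -0.50 and Bin1 at -0.45. Wnt and beta-catenin genes stood at 0.027 (percentile 47.9), autophagy and lysosome genes at -0.031 (percentile 13.1), axon injury and regeneration genes at 0.17 (percentile 85.6), interferon response genes at -0.0038 (percentile 33.6) and sex-linked genes at 0.0025 (percentile 41.2). Interferon response genes left the range over genes with 1 UMI in each library (-0.50), and sex-linked genes in male nuclei (-0.28). Of the lists of glial genes, 3 had medians at percentile 0, myelin at -2.75 (all 19 members at least 1.5-fold lower), homeostatic microglia at -0.87 and astrocyte homeostasis at -0.62. Free RNA subtraction put these inside the random range, at -1.45, -0.13 and -0.50, but with the lower estimate all 3 stayed below it, at -2.79, -0.58 and -0.56. A minimum of 200 UMIs also put homeostatic microglia inside it (-0.16). Disease-associated microglia genes stood at -0.24 (percentile 0.25), with 2 of 13 higher and 4 lower, turned to 0.11 in thinned nuclei and 0.17 after subtraction (-0.13, inside the range, with the lower estimate), and lay inside the range in female (-0.13) and male nuclei (-0.047). Reactive astrocyte genes lay inside the range (-0.25, percentile 9.18), with none of 4 measured members past 1.5-fold, and left it in female nuclei (-0.66) and over genes with 1 UMI in each library (-0.81).

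**Figure D4:**
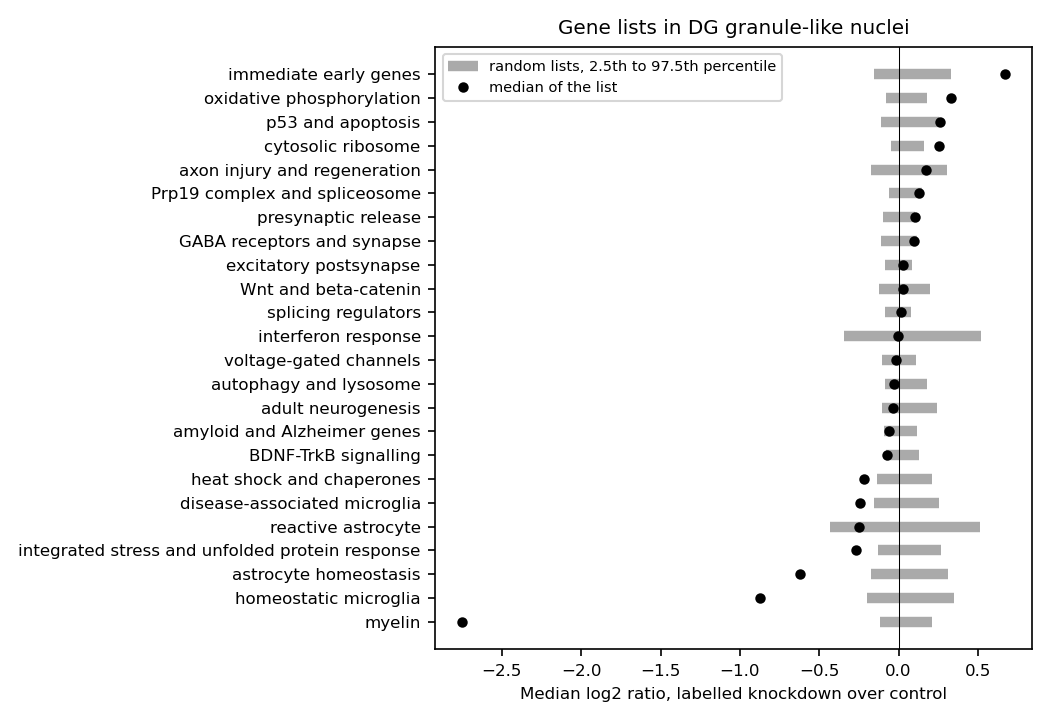
Median log2 ratio (knockdown-labelled library over control) of each gene list but the sex-linked one in DG granule-like nuclei (points), with the central 95% of 10000 matched random lists (grey bars). Immediate early genes lie at 0.67, BDNF-TrkB signalling at -0.075 and myelin at -2.75.

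The 10 highest DG granule-like genes by the fixed rule were Egr4, Wfs1, Cpne7, Sv2b, Arc, Stmn2, Cck, Resp18, Ociad2 and Nrsn2, with log2 ratios of 1.78 to 2.49. Several are known from other neurons, such as Wfs1 in CA1 pyramidal cells and the neuropeptide gene Cck in interneurons. Of these 10, 8 stood below 0.25 of the level of some other cluster, and free RNA subtraction turned Cpne7, Sv2b and Arc below 0, of which Cpne7 (1.23) and Arc (1.45) stayed above 0 with the lower estimate. With the added condition on every cluster, Resp18 (1.89) and Nrsn2 (1.78) led, followed by Cyb561 (1.74), Zfp57 (1.56) and Tdrd5 (1.56). The 10 lowest were Abca2, Spata13, Rgs6, Khsrp, Oprd1, Gprc5b, Kcnh4, Mrps6, Chd7 and Pdia4, with log2 ratios of -1.27 to -0.84, and all of them stayed below 0 after either subtraction and in nuclei of either sex. Abca2, a lipid transporter gene of myelinating glia, and Chd7 stood below 0.25 of their highest cluster level. Khsrp, which encodes an RNA-binding protein of splicing and mRNA decay, was 46.3 against 92.3 CPM (-0.996, -1.18 to -0.81) and Kcnh4, a potassium channel gene, 12.7 against 24.1 CPM (-0.93, -1.29 to -0.56). Oprd1, the delta opioid receptor gene, was 12.4 against 24.1 CPM (-0.96), and 0.086 with nuclei thinned to 1000 UMIs.

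GABAergic-like nuclei rested on 103 control nuclei against 1951, and clusters 11, 13, 16 and 17 held 31.2%, 26.7%, 23.3% and 18.8% of them in the knockdown-labelled library and 18.4%, 47.6%, 7.77% and 26.2% in the control. Col5a2, a collagen gene, was 45.5 against 0.927 CPM (5.03, 3.13 to 10.92, from 771 UMIs and 1), and Mageb18 was 17.3 against 0.927 CPM. Fam240b, Tchh and Spink8 had no UMI in the control. Against a floor of 3 UMIs over that class they were at least 4.16-fold, 3.27-fold and 2.61-fold higher. Free RNA subtraction lowered the log2 ratio of Spink8 from 3.975 to 1.73, or to 2.78 with the lower estimate. After subtraction at the median estimate Col5a2 stood at 6.49, Fam240b at 4.79, Tchh at 4.15 and Mageb18 at 3.92. Ebf1 (-3.36), Otx2os1 (-3.35), Nwd2 (-2.32), Dach1 (-1.89) and Unc13c (-1.57) were lowest. The control values of these genes came from few nuclei, with Ebf1 detected in 9.71% and Otx2os1 in 17.5% of the 103. Nwd2 was detected about as often in both libraries (22.0% and 21.4%). Of the 5 highest GABAergic-like genes 2 did not meet the added condition on every cluster, and of the 5 lowest 2 did not. Named as at least 1.5-fold higher in both compared neuronal classes were Egr4, Wfs1, Cck, Asb18, Rprml, Ano2, Arc, Vgf, Vwa5b2 and Moxd1, with Vgf, an activity-regulated neuropeptide precursor gene, at 1.64 and 1.18. Named as lower in both were Abca2 and Neo1, a guidance receptor gene (-0.61 and -0.69). Neo1 was under 1.5-fold lower in male nuclei (-0.15 and -0.34), against -1.74 and -1.21 in female nuclei. The numbers of such genes are not compared, since the minimum of 100 UMIs is a higher level in the control, with 1078783 UMIs in GABAergic-like nuclei, than in the other library with 16945273.

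In GABAergic-like nuclei the heat shock list had a median of -0.39 (percentile 0.12), with 3 of 13 members at least 1.5-fold lower and none higher, and adult neurogenesis one of -0.26 (percentile 0.35), with 7 of 20 lower and 1 higher. The Prp19 complex and spliceosome stood at 0.26 (percentile 99.9), with 3 of 32 higher and 2 lower, and excitatory postsynapse at 0.17 (percentile 99.5), with 2 of 29 higher and 1 lower. Nnat (-1.33) and Prox1 (-0.82) were lower and Neurod2 (1.69) higher among the neurogenesis genes. With libraries centred before clustering the neurogenesis median was 0.076, and it lay inside the random range at resolution 2 (-0.22) and over genes with 200 UMIs (-0.15). The postsynapse list lay inside it with free RNA subtracted (-0.061, or 0.041 with the lower estimate), with nuclei thinned (0.0045) and at resolution 2 (0.10), the heat shock list with free RNA subtracted (-0.23, but -0.35 and outside with the lower estimate), with nuclei thinned (-0.22) and at resolution 2 (-0.22), and the Prp19 list with doublets kept (0.11).

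The highest genes by the fixed rule in every glial class were mostly ones known from neurons. In oligodendrocyte-like nuclei they were Cpne7 (4.795), Neurod6 (4.54), Resp18 (4.30), Tmem158 (4.18) and Sv2b (4.12). In astrocyte-like nuclei they were Tmem59l (4.14), Chgb, Caly, Mir124a-1hg and Snap25, in OPC-like nuclei Chgb (3.39), Atp1b1, Tmem59l, Nrgn and Olfm1, and in microglia-like nuclei Snhg11 (4.05), Atp1b1, Ly6h, Snap25 and Pcsk2. Synaptic lists shared this, with excitatory postsynapse medians of 2.32 in oligodendrocyte-like, 1.88 in microglia-like, 1.10 in astrocyte-like and 0.30 in OPC-like nuclei. The glial values below stand beside that neuronal RNA.

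In microglia-like nuclei, homeostatic microglia genes had a median of -0.85 (percentile 0), with 10 of 15 at least 1.5-fold lower and none higher. The same list lay below the random range in all 6 compared classes, at -1.36 in oligodendrocyte-like, -0.87 in DG granule-like, -0.60 in GABAergic-like, -0.54 in astrocyte-like and -0.53 in OPC-like nuclei. That call ended in OPC-like nuclei when thinned (0.088, percentile 65.6) or over genes with 200 UMIs (0.027, percentile 66.1), in astrocyte-like nuclei under the same settings (-0.22 and -0.13), and in DG granule-like and GABAergic-like nuclei with free RNA subtracted (-0.13 and -0.26), in the former also over genes with 200 UMIs (-0.16) but not with the lower estimate of free RNA (-0.58). Among the lower members in microglia-like nuclei were P2ry13 (-1.35), Sall1, a transcription factor gene of microglial identity (-1.18), Olfml3 (-1.16) and Selplg (-1.15). Disease-associated microglia genes had a median of 0.061 (percentile 81.6), with 1 member at least 1.5-fold higher, 1 lower and 13 within 1.5-fold, the higher one being Timp2 (0.64) and the lower one Trem2, a lipid receptor gene (-0.85, -1.29 to -0.45). Trim65 (-2.31), Pllp, Ccdc192 and Gpr37 were among the lowest microglial genes, of which Pllp and Gpr37 are known from myelinating cells. Amyloid and Alzheimer genes lay above the range in microglia-like nuclei (0.17, percentile 99.3), with 6 of 26 higher and 1 lower. They lay inside it with doublets kept (0.027), the stricter filter (0.15) and genes with 200 UMIs (-0.0089). These microglia-like values compare mostly cluster 12 with cluster 9.

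In oligodendrocyte-like nuclei, mostly of cluster 4 against clusters 0, 2 and 3, myelin genes had a median of -0.56 (percentile 0), with 9 of 19 at least 1.5-fold lower and none higher, such as Ugt8a (-1.09), and that list too lay below the random range in all 6 classes, except in DG granule-like nuclei with free RNA subtracted at the median estimate (-1.45, against -2.79 with the lower one). Heat shock genes had a median of -0.76 (percentile 0), with 9 of 15 lower, including Hspa1b (-2.96), Hspa1a (-2.88) and Bag3 (-1.45). The lowest genes were Bfsp2 (-2.50), Aldh1l2, Aebp1, Il17rb and Serpinb1a (-1.53). Astrocyte-like nuclei, of cluster 5 alone, had Pde10a at 475 against 1389 CPM (-1.55), Gpr37 (-1.57), Tnc (-1.17), Olfml1 (-1.10) and Golga7 (-1.09) as the lowest genes, with Tnc at 0.23 when only male nuclei were taken. Gfap, the intermediate filament gene raised in reactive astrocytes, was 77.4 against 117 CPM (-0.59, -0.91 to -0.28), and the reactive astrocyte list stayed inside the random range (median -0.30, percentile 2.91), with 3 of 7 measured members at least 1.5-fold lower and 1 higher. It left the range as mean CPM over nuclei (-0.46), with the looser filter (-0.34) and with libraries centred (-0.29), and was 0.047 with nuclei thinned. Its member Fbln5 went the other way, with 78.7 against 24.8 CPM (1.66). OPC-like nuclei had Abca2 (-1.42), Lims2 (-1.41), Acaa1a, Cdan1 and Ahsa2 as the lowest genes, and a Wnt and beta-catenin median of -0.26 (percentile 0.07), although 2 of 22 members were at least 1.5-fold higher and none lower. That median lay inside the random range over genes with 200 UMIs (-0.017) or with 1 UMI in each library (-0.12), and with nuclei thinned (-0.23).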

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

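In this part, the comparison of list directions between neuronal and glial classes was widened from DG granule-like nuclei to both neuronal classes after the first gave nothing, the test of exchanged labels and that of olfactory-type neuroblasts were chosen only after the results they bear on were seen, and the subtraction of free RNA and the shorter lists of granule-lineage genes were alternatives chosen after seeing the data.

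The adult neurogenesis list had medians of opposite sign between classes, at -0.26 (percentile 0.35) in GABAergic-like nuclei against 0.92 (percentile 99.9) in oligodendrocyte-like and 0.55 (percentile 99.3) in microglia-like nuclei. The difference between classes was not tested, and the GABAergic-like median was 0.076 with libraries centred. The oligodendrocyte-like one lay inside the random range over genes with 200 UMIs (0.16, percentile 63.2), with nuclei thinned (0.17) and with the stricter filter (0.40, percentile 92.3). In oligodendrocyte-like nuclei Neurod2 (3.69), Stmn2 (2.87) and Tubb3 (2.74), known from neurons, were among its higher members. In microglia-like nuclei 4 of 9 measured members were at least 1.5-fold higher and 2 lower, Sox4 (-1.65) and Marcks (-0.82). The median there turned to -0.34 (percentile 12.6) with nuclei thinned to 1000 UMIs, where 4 members were left.

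Transcripts of neurons were higher in the glial nuclei of the knockdown-labelled library. Doublets left in those classes would sit in few nuclei, but the median nucleus held 0.930 to 1.03 of the mean number of UMIs of 10 neuronal genes. This argues against doublets as the source of most of these UMIs. The count was of all such UMIs in the knockdown-labelled library, not of the excess over the control. It therefore cannot exclude that doublets carried part of that excess. Free RNA from neurons should bring markers of GABAergic, CA1 and DG neurons at about 1 share of their library level. The shares differed by up to 4.15 times, in OPC-like nuclei on 2 to 5 markers each, and by between 2 and 3 times in the other glial classes. The DG set was the highest in every glial class, at 27.9% to 71.9%, against 11.8% to 23.2% for the other sets. Glia themselves express many such markers, so this spread cannot count against free RNA. Free RNA as the whole source can neither be excluded nor shown. A response of glia to loss of Bcas2 in neurons stays open and was not tested.

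Bcas2 was within counting error of the control in DG granule-like nuclei of the library labelled knockdown. After free RNA subtraction its log2 ratio was -0.21, between the bounds set in advance for and against a masked loss, and with the lower estimate of free RNA -0.12, past the bound against it. The 2 estimates thus disagree, and a loss hidden by free RNA cannot be told apart from no loss. Exchanged labels would leave Bcas2 higher in the knockdown-labelled library, and the interval of the log2 ratio, from -0.32 to 0.24, decides neither. Cre in only part of the neurons, and a deletion that leaves the 3' tag in place, were not tested and stay open.

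Neuroblast-like nuclei were 0.151 per 100 DG granule-like nuclei in the knockdown-labelled library and 16.5 in the control, and removal of doublets is argued against, since with doublets kept the ratio of these rates was still 0.0524 (0.0425 with the stricter filter). Olfactory-type neuroblasts from tissue beside the hippocampus stay open for part of the control's nuclei, which held, summed over genes, more UMIs of Meis2 (526), Dlx6os1 (164), Gad2 (56) and Dlx1 (42) than of Prox1 (114), Neurod1 (29) and Eomes (17), with Dlx6os1 and Meis2 among the leading genes of the cluster, and 37 of the 89 nuclei and all 3 of the knockdown-labelled library were of the olfactory kind. Detection of single genes decides little, since Meis2 was found in 38 and Dlx6os1 in 29 of the 89 nuclei, and Prox1 in 44, Neurod1 in 18 and Eomes in 8. Olfactory-type neuroblasts are argued against as the whole source only in that 58.4% of the 89 held more UMIs of granule-lineage than of olfactory-lineage genes. That share was 53.9% without Rbfox3 and Rfx3, and 48.3% with Prox1, Neurod1, Eomes and Neurog2 alone. Free RNA of granule cells could add to these shares, and so could Prox1 RNA of other classes. Over all nuclei Prox1 was higher in the control, which had 538 DG granule-like nuclei, than in the other library, which had 1988. Prox1 thus did not follow the number of these nuclei, which weakens the argument from the shares. Neurons of the named classes, which can themselves express such genes, made up 56.5% and 8.24% of all nuclei. Over all nuclei, Draxin (1.10 against 5.13 CPM), Top2a (1.09 against 3.80), Sox4 (7.80 against 24.5) and Prox1 (63.9 against 125) were lower in the knockdown-labelled library. Igfbpl1 (9.25 against 8.94), Eomes (1.39 against 1.33) and Mki67 (3.38 against 3.35) were close. Dcx (50.1 against 17.4), Sox11 (28.1 against 12.6) and Neurod1 (12.2 against 7.60) were higher. These values decide nothing, and a lower number of neuroblasts after Bcas2 loss is a hypothesis that dissection and the sort leave open.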

How the results depend on the processing

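The free RNA subtraction, the split by sex, shorter lineage lists and thinning with the genes of the unthinned sums were chosen after seeing the data, and the cause of each change below was not tested unless given. Of the 138 values of the 12 main results under alternatives, 107 lay within counting error, kept their direction outside the random range, or stayed inside it in either direction. Bcas2 in DG granule-like nuclei stayed between -0.56 and 0.036 and Bdnf there between -0.070 and 0.10. Thinning to 1000 UMIs put Bcas2 at -0.56 (55 against 22 UMIs) in DG granule-like nuclei and -0.23 in all neurons, with few UMIs left. The gap in neurons of the named classes, 48.2 points, was 37.5 with the looser filter, 61.7 with the stricter one and 43.2 with doublets kept. It was 46.2 and 42.7 at resolutions 0.5 and 2, and 44.5 with libraries centred. The oligodendrocyte-like gap of -46.0 points was -49.5 and -51.1 with the looser and stricter filters, the DG granule-like gap of 11.3 was 8.07 and 13.5, and the neuroblast-like gap of -0.773 was -0.583 with doublets kept and -1.09 with libraries centred. Ntrk2 in DG granule-like nuclei (0.38) was 0.54 with doublets kept, 0.52 in female and 0.24 in male nuclei, 0.13 with the lower subtraction and -0.16 with the other. Ntrk2 turned to -0.11 at resolution 2 and -0.12 with libraries centred in GABAergic-like nuclei, and to -0.0070 with TMM scaling and -0.027 in male nuclei in astrocyte-like nuclei. The BDNF-TrkB list in DG granule-like nuclei (-0.075) left the random range at -0.081 with the stricter filter, -0.082 at resolution 2, -0.079 as mean CPM, -0.10 with the lower subtraction, and -0.20 and -0.16 thinned, without and with the unthinned genes. The Prp19 list there (0.13) left it at 0.15 with doublets kept and at 0.18 and 0.17 with the 2 subtractions. Immediate early genes there turned to -0.054 thinned, where 5 members were left (0.65 with the unthinned genes), to -0.19 subtracted, and were 0.32, inside the range, with the lower subtraction. Other medians turned sign: adult neurogenesis to 0.076 in GABAergic-like nuclei with libraries centred and to -0.34 in microglia-like nuclei thinned; splicing regulators with TMM scaling to -0.020 in astrocyte-like and -0.10 in oligodendrocyte-like nuclei; amyloid and Alzheimer genes in microglia-like nuclei to -0.00054 with TMM scaling and -0.0089 with 200 UMIs per gene; disease-associated microglia genes in DG granule-like nuclei to 0.11 and 0.018 thinned and 0.17 subtracted; OPC-like voltage-gated channels to -0.0059 and homeostatic microglia genes to 0.088 thinned, the latter to 0.027 with 200 UMIs; and the GABAergic-like postsynapse list to -0.061 subtracted. Among named genes, Oprd1 turned to 0.086 thinned, Cpne7, Sv2b and Arc to -7.42, -5.84 and -0.19 subtracted, Sv2b to -6.40 with the lower subtraction, and Tnc to 0.23 in male nuclei. TMM scaling shifts all genes of a class alike, and left the percentiles of the splicing regulators (99.0 and 99.9) and amyloid genes (99.3) unchanged. Of the other results, 2128 kept, 132 moved, 85 were weaker and 45 stronger. No value was had for Bdnf in GABAergic-like nuclei thinned, at resolution 2 and subtracted, for CA3-like shares with doublets kept and at resolution 0.5, and for some lists left with too few genes. No paired analysis was possible because each group has 1 library. Depth limits Bcas2 in particular, with 48 control UMIs in GABAergic-like nuclei.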

Other observations

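In this part no test was planned before the data were examined, and the genes were chosen after their values were seen.

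Of 9976 genes with at least 20 UMIs over both libraries in each of the 6 compared classes, 5 were at least 2-fold higher in the knockdown-labelled library in every class and 5 at least 2-fold lower. The higher genes were Neurod6, Cck, Gm32647, Timm8b and Wfs1. Neurod6, a transcription factor gene of pyramidal neurons, and Cck and Wfs1 are neuronal, and Neurod6 was 13.2 against 0.482 CPM in DG granule-like and 49.3 against 2.09 CPM in oligodendrocyte-like nuclei. Timm8b, a mitochondrial import gene, was 15.6 against 7.47 CPM in DG granule-like and 24.6 against 11.1 CPM in oligodendrocyte-like nuclei. The lower genes were Cryab, Gm44866, E330020D12Rik, Samd1 and Selplg. Cryab was 142 against 384 CPM in oligodendrocyte-like nuclei, where it is highest, and 3.74 against 32.1 CPM in DG granule-like nuclei. Selplg, a microglial adhesion gene, was 407 against 903 CPM in microglia-like nuclei. Samd1 was low everywhere, at 1.68 against 5.55 CPM in DG granule-like and 3.88 against 10.1 CPM in oligodendrocyte-like nuclei.

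Both libraries held nuclei of both sexes by Xist and Y-linked genes. Female nuclei were 42.9% of those called in the knockdown-labelled library and 54.2% in the control, and in DG granule-like nuclei 41.0% and 47.9%. In DG granule-like nuclei of each sex apart, the immediate early gene median was 0.90 in female and 0.64 in male nuclei, and the oxidative phosphorylation median 0.25 and 0.34. The log2 ratio of Neo1 there was -1.74 in female and -0.15 in male nuclei, and in astrocyte-like nuclei the values of Neo1 were -1.47 and -0.54.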
